A study of Mus musculus with 4 samples.

How the data were processed

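The series holds RNA sequencing of exosomes from bone marrow MSCs of male SD rats, with 2 libraries from cells given DMSO (MSC-Exo) and 2 from cells pretreated with 1 µmol/L atorvastatin (MSCATV-Exo). The samples are registered under mouse, but the growth protocol, the genome build and the feature identifiers are all of rat, and the data were treated as rat. Cells were used at passages 3 to 4 per the labels. The labels give the pretreatment as 24 h in the sample characteristics and the design text and as 48 h in the treatment protocol, so its length is uncertain. Exosomes were obtained from conditioned medium, and both ultracentrifugation and a commercial isolation reagent are described. Libraries were made from total RNA with the NEBNext Ultra kit, which does not mark the strand. The labels name no separate animals or cultures behind the 2 libraries of a group. The SDs, the SEs and the edgeR and DESeq2 p-values of single features below therefore measure the spread between these libraries alone. No error, interval or p-value below can be read as a spread between animals or cultures.

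Per the submitters' processing notes, TopHat2 was used with the rat genome build, named both as rn6 and as Rnor_6.0. The notes used here give no TopHat2 version, read counter or annotation release. The authors deposited raw read counts per gene (42977 genes) and per non-coding transcript (18408 features) as whole numbers. Beside them the authors deposited RPKM values, reads scaled by feature length and library total. Recomputing RPKM from counts and lengths gave a library total equal to the sum of the gene counts for the gene table. For the ncRNA table the total was 8940773, 9007642, 9648244 and 9388677 in MSC-Exo replicates 1 and 2 and MSCATV-Exo replicates 1 and 2, larger than that table's own sums, so those RPKM values rest on a wider feature set. The deposited comparison tables give mean RPKM per group, a log2 ratio of those means without a pseudocount, and a p-value and q-value per the file headers; the test behind the deposited p-value and q-value is not stated. Where a group mean is 0, the deposited log2 ratio is infinite (1165 genes). In the authors' comparison, 12 gene names had no match because the expression table holds them as spreadsheet dates. Genes and transcripts are named and placed by the deposited tables themselves, since the reference tables at hand were of mouse and were not used.

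The gene counts summed to 5350295, 5355098, 5947020 and 5598378 in the order above, and the ncRNA counts to 3075773, 3038528, 3523815 and 3150293. A count of 0 allows up to 3 counts, or 0.504 to 0.561 CPM. These floors cover counting error only, since reads without molecular identifiers are not independent molecules.

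Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood F test, two-sided, Benjamini-Hochberg adjusted p under 0.05), separately for 33480 genes and 13128 ncRNAs. The biological coefficient of variation was 0.559 for genes and 0.621 for ncRNAs. Log2 fold changes are MSCATV-Exo over MSC-Exo, SE is the standard error of the fit, and CPM are counts scaled to a common library total with the TMM factors. Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 22 lists with at least 5 tested members, with fry beside it. The lists reported here covered cholesterol synthesis, YAP and SRF targets, MSC markers, extracellular matrix, exosome genes, angiogenic and paracrine factors, inflammation, proliferation, apoptosis, imprinted genes, known lncRNAs, ribosomal proteins, nuclear oxidative phosphorylation genes, core histones, and markers of leukocytes, erythroid, endothelial, adipocyte, osteoblast and hepatocyte cells and of other tissues. Of the structural RNA list 3 members were tested and of the mitochondrially encoded list 0 were found under their symbols, so neither had a list test. The count test was checked on simulated data with 200 changed features at 32 CPM or more. The counts were drawn at the trended dispersion, without a spread particular to each feature. With genes, edgeR recovered 2 of 100 changed 2-fold and 65 of 100 changed 4-fold with 1 false call, and with ncRNAs 0 and 10 of 100 with 0 false calls.

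Alternatives were DESeq2 1.42.0, RLE factors, total counts without a factor, no filter on low counts, a mean of at least 1 CPM, the replicate number as a block, leaving out each library, limma on log2(RPKM + 1) and log2(RPKM + 0.1) for features with a mean RPKM of at least 1, and the authors' calls. Without TMM the median log2 fold change of all genes moved from -0.01 to -0.11. After the data were seen 2 alternatives were added, without rRNA features and with only the features above a mean of 8.17 RPKM (genes) or 6.86 RPKM (ncRNAs), which is 3 times the median of olfactory receptor genes or of ncRNAs.

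Genes were named by a rule fixed before the data were examined. It took 15 genes of prior interest, of which 3 were not found, then the 10 higher and 10 lower genes and the 5 higher and 5 lower ncRNAs past the threshold, filled, where too few passed, by the smallest p among features whose groups did not overlap. It also took up to 4 members of each list with the smallest p and the 10 most abundant genes and ncRNAs. Pairs of single libraries were compared by a two-sided exact binomial test of reads per gene, given the library totals, on the 38274 genes with at least 10 reads over the 4 libraries (Benjamini-Hochberg adjusted p under 0.05). In simulated pairs without a difference it called 0 genes, and it recovered 200 of 200 genes changed 4-fold. Descriptive values were computed with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures with matplotlib 3.10.9.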

Results

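RNA was sequenced from exosomes, small vesicles pelleted from conditioned medium, that were shed by cultured rat bone marrow mesenchymal stem cells (MSCs). The 2 MSC-Exo libraries came from cells given the solvent DMSO, and the 2 MSCATV-Exo libraries came from cells pretreated with 1 µmol/L atorvastatin, a cholesterol-lowering drug of the statin class. The gene table held 5350295 and 5355098 counts in MSC-Exo replicates 1 and 2 and 5947020 and 5598378 in MSCATV-Exo replicates 1 and 2. The ncRNA table, which lists non-coding transcripts, held 3075773, 3038528, 3523815 and 3150293 counts in the same order. At least 1 count was recorded for 36573, 37318, 34813 and 36170 of the 42977 genes, and 2990 genes stood at 0 in all 4 libraries. The series title names long non-coding RNAs (lncRNAs) as its subject, so the comparison asked which lncRNAs and which other transcripts differed between exosomes of treated and untreated cells.

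Characterised genes among those with separated groups and the smallest p included Calr, Atf5, Cald1 and Myc, higher in MSCATV-Exo, and Fam111a and Stoml2, lower. Calr, which encodes the endoplasmic reticulum chaperone calreticulin (chromosome 19, 25956771 to 25961666, minus strand), averaged 163 ± 24.3 normalised CPM (SD, n = 2) in MSC-Exo and 327 ± 16.6 in MSCATV-Exo, a log2 fold change of 1.01 ± 0.20 (SE). Atf5, a transcription factor of the stress response, went from 523 ± 11.4 to 827 ± 4.40 CPM (log2 fold change 0.66). Cald1, which encodes the actin-binding protein caldesmon, went from 529 ± 9.06 to 832 ± 55.0 CPM (0.65). Myc, a transcription factor of cell growth, had 15 and 21 counts in MSC-Exo and 123 and 116 in MSCATV-Exo (log2 fold change 2.72 ± 0.59, SE). Its group means of 1.44 RPKM in MSC-Exo and 8.84 in MSCATV-Exo lay on either side of 4.76, the median of protein-coding genes. Fold changes near that level may not follow expression. On the other side, Fam111a (chromosome 1, 229003778 to 229019532, plus strand), which encodes a protease, had 424 and 351 counts in MSC-Exo and 26 and 70 in MSCATV-Exo (log2 fold change -3.02 ± 0.44, SE). Stoml2, which encodes a protein of the mitochondrial inner membrane, had 107 and 77 against 10 and 5 (-3.59 ± 0.78, SE).

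None of these genes passed the threshold of the edgeR test, in which 0 of 33480 genes had an adjusted p under 0.05. Of those genes, 1236 had an unadjusted p under 0.05 where 1674 would fall there by chance, and the smallest adjusted p was 0.997. DESeq2 on the same counts called 106 genes, 51 higher and 55 lower in MSCATV-Exo, and Calr (adjusted p = 1.12e-06), Atf5 (1.30e-07), Cald1 (2.27e-06), Myc (0.000724), Fam111a (3.69e-09) and Stoml2 (0.000724) were all among them. The groups did not overlap for 11223 of the 33480 genes (33.5%), and chance gives 33.3% with 2 libraries against 2. A simulation at this depth used the trended dispersion, with 200 genes changed at 32 CPM or more. In it edgeR recovered 65 of 100 genes changed 4-fold and 2 of 100 changed 2-fold. It gave no gene a spread of its own, so these shares may be too high for the real data. The count of 0 became 1 without MSC-Exo replicate 1, 2 without MSC-Exo replicate 2, 27 without MSCATV-Exo replicate 1 and 168 without MSCATV-Exo replicate 2. Of the 6 genes named above, Fam111a was called without either MSCATV-Exo library, Stoml2 without replicate 1 and Calr without replicate 2 of that group.

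**Figure D1:**
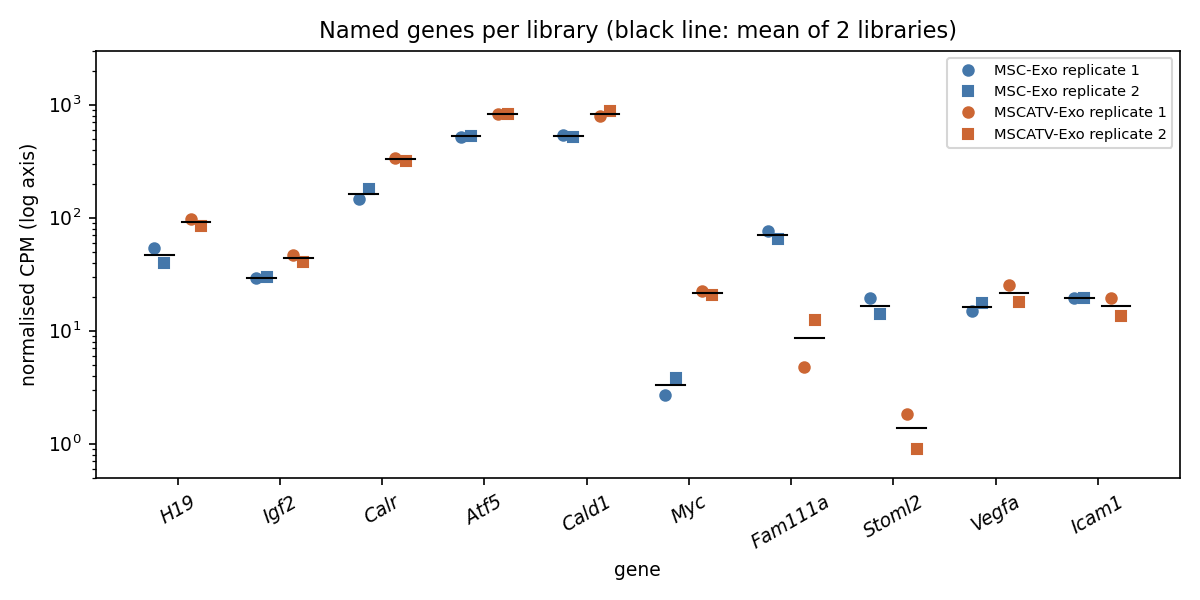
Normalised CPM (log axis) of 10 named genes in each of the 4 libraries; points are libraries, coloured by group, and black lines are the means of 2 libraries. H19 stood at 54.0 and 39.4 CPM in MSC-Exo and at 97.9 and 84.5 CPM in MSCATV-Exo.

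The remaining genes picked by the smallest p among those with separated groups were mostly uncharacterised loci and pseudogenes. LOC257642, annotated as an rRNA promoter binding protein, averaged 42945 ± 3587 CPM in MSC-Exo and 54338 ± 1841 in MSCATV-Exo (log2 fold change 0.34 ± 0.05, SE). Neither the edgeR test on all 4 libraries nor DESeq2 called it. Among the other fits on all 4 libraries, edgeR with the replicate block or with no filter on low counts did. With a library left out its log2 fold change was 0.25 to 0.43. Its sequence could not be compared with that of rRNA, so its reads may be rRNA reads, and it was left out of the abundant protein-coding genes below. LOC102547206 (12.4 ± 1.03 against 49.9 ± 2.97 CPM) and Clic6, which encodes a chloride channel (7.80 ± 1.10 against 33.4 ± 17.0 CPM), were higher in MSCATV-Exo with log2 fold changes of 2.00 and 2.09. Detected in MSCATV-Exo alone were the lncRNA LOC102546313 (36 and 94 counts), the V segment LOC100361226 (55 and 41) and the ribosomal protein L5 pseudogene LOC690150 (62 and 31). Against a floor of 3 counts over the MSC-Exo group these were at least 43.2-fold, 31.9-fold and 30.9-fold higher. Such bounds, here and below, cover counting error alone and not the spread between libraries. Lower in MSCATV-Exo were LOC689258 (log2 fold change -1.54) and the lncRNAs LOC103692954 (-2.23) and LOC102549857 (-3.58). Pseudogenes of thymosin beta-10 (LOC108351718), ferritin light chain 1 (LOC108351202), choline-phosphate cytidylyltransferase (LOC365846), ubiquitin-conjugating enzyme E2 S (LOC103694411) and ribosomal protein S26 (RGD1562835) were at 0 in both MSCATV-Exo libraries and, against a floor of 3 counts over the group, at least 30.1-fold to 32.8-fold lower. Reads of a processed pseudogene can be shared with its parent gene, and the tables do not say how such reads were assigned.

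H19, an imprinted lncRNA (chromosome 1, 215744404 to 215747080, minus strand), was higher in both MSCATV-Exo libraries than in either MSC-Exo library. Its counts were 300 and 216 in MSC-Exo and 535 and 474 in MSCATV-Exo, or 46.7 ± 10.3 against 91.2 ± 9.48 CPM (SD, n = 2), a 1.95-fold difference with a log2 fold change of 0.96 ± 0.28 (SE). Igf2, the growth factor gene next to H19 in the same imprinted cluster, averaged 29.5 ± 0.673 against 43.8 ± 4.64 CPM (log2 fold change 0.57 ± 0.31, SE), with both MSCATV-Exo libraries above both MSC-Exo libraries. The edgeR p for H19 was 0.00601, which gave 1.00 after adjustment over all genes and 0.0421 when adjusted over the list alone, a list of 7 tested lncRNAs in which H19 was the 1 gene to pass. Adjusted over the list of 11 imprinted genes, which also holds H19, it was 0.0661 and did not pass. H19 had been placed on the lncRNA list because of the study's subject. Of 33 symbols fixed for that list, 10 were found and 7 passed the count filter. A filter at a mean of at least 1 CPM kept 9, over which this adjustment was not run. Adjustment over a list alone was not corrected for the number of lists, and no other list had a member that passed it. DESeq2 gave H19 an adjusted p of 0.0385, and the H19 transcript in the ncRNA table had a log2 fold change of 1.00 ± 0.31 (SE) with a DESeq2 adjusted p of 0.0397. Its edgeR p before adjustment was 0.00836. In the lncRNA list Miat was at -0.40 ± 0.31 (SE; -0.77 to -0.10 with a library left out), Mir155hg at 1.02 ± 0.92 (-0.29 to 1.86) and Tug1 at 0.70 ± 0.66 (0.26 to 1.33), and the list as a whole was not called (5 of 7 higher, camera adjusted p = 0.661), its median of 0.11 turning to -0.02 with total-count scaling. With a library left out the median went from -0.08 (3 of 8 higher, without MSCATV-Exo replicate 1) to 0.86 (5 of 9, without MSCATV-Exo replicate 2) and 1.20 (7 of 9, without MSC-Exo replicate 1). Malat1, Neat1 and Meg3 were not found under those symbols and were not analysed here. Of 11 tested imprinted genes, 9 were higher in MSCATV-Exo, including Dlk1 (0.81) and Grb10 (0.41), and the list was not called (median log2 fold change 0.41, camera adjusted p = 0.267). The number was 8 of 11 (median 0.19) with limma on log2(RPKM + 1) and 7 of 11 (0.22) with limma on log2(RPKM + 0.1). Without MSC-Exo replicate 1 it was 6 of 11 (median 0.27), and Dlk1 ranged from 0.38 without MSCATV-Exo replicate 2 to 1.13 without MSCATV-Exo replicate 1.

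Among non-coding transcripts, 0 of 13128 passed the edgeR test, 463 had an unadjusted p under 0.05 where 656 were due by chance, and DESeq2 called 31, 6 higher and 25 lower. The groups were separated for 33.5% of the transcripts, against 33.3% by chance. Among the transcripts with separated groups and the smallest p were, on the higher side, a non-coding transcript of Mall (XR_352582.3, 6 and 17 counts against 110 and 65, log2 fold change 2.94), the pseudogene transcript ENSRNOT00000037179 (2.90) and XR_001840112.1 of LOC102551940 (2.29). The transcript of LOC102546313 and XR_352602.3 of LOC102547080 were at 0 in MSC-Exo and at least 44.1-fold and 20.4-fold higher in MSCATV-Exo against a floor of 3 counts over the group. On the lower side were the transcripts of LOC689258 (157 ± 42.7 against 55.3 ± 3.38 CPM; SD, n = 2) and LOC103692954 (log2 fold change -2.19), 2 isoforms of LOC102547903 with the same counts in every library (-2.62), and XR_595959.2 of LOC100909672, at 0 in MSCATV-Exo and at least 33.7-fold lower. The edgeR count was 0 without MSC-Exo replicate 1, 3 without MSC-Exo replicate 2, 16 without MSCATV-Exo replicate 1 and 69 without MSCATV-Exo replicate 2.

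Genes of cholesterol synthesis, which cells raise when sterols run short, were not called as a list. Of 25 tested members 18 were higher and 7 lower in MSCATV-Exo, the median log2 fold change was 0.14 and the mean -0.05 (camera adjusted p = 0.661). With total-count scaling 14 were higher and 11 lower (median 0.02), without MSC-Exo replicate 1 also 14 and 11 (median 0.21), and without MSCATV-Exo replicate 2 it was 16 and 9 (0.26). The median RPKM of the list was 5.00 to 5.66 over the 4 libraries, near that of all protein-coding genes (4.12 to 4.74). Only 3 members were kept when features above a mean of 8.17 RPKM alone were tested, with a median log2 fold change of -0.17. Most values of this list may therefore not follow expression. Hmgcs1 was at 0.80 ± 0.67 (0.21 to 1.80 with a library left out), Insig1 at 0.38 ± 0.57 (0.14 to 0.62), Stard4 at 0.80 ± 0.43 (0.47 to 1.22) and Cyp51 at 0.65 ± 0.47 (SE), while Ebp was at -1.54 ± 1.04 (-2.06 to -0.72). Idi1, an isomerase of the mevalonate pathway, was the member with the smallest p, at 19 and 94 counts against 0 and 4 (log2 fold change -4.76; edgeR adjusted p = 0.192 when adjusted over the list alone). With a library left out its log2 fold change ranged from -8.83 to -3.18. It passed the threshold over all genes without MSCATV-Exo replicate 2, where the lone MSCATV-Exo library stood at 0 and the value of -8.83 gives no size, and with no other library left out. The transcription factor gene Klf2 was at 0.49 ± 0.89 (SE; 0.31 to 0.69 with a library left out).

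Ribosomal protein genes were the 1 list that camera called, with 72 of 85 tested members higher in MSCATV-Exo, 13 lower and a median log2 fold change of 0.29 (adjusted p = 0.00203 over 22 lists). The call was lost with adjusted p = 0.916 with an estimated correlation, and fry, which tests whether the members move in the same direction on balance, gave p = 0.196. Rps24 (33.7 ± 4.80 against 71.7 ± 7.23 CPM, log2 fold change 1.09), Rps10 (0.97), Rpl17 (0.86) and Rplp0 (0.48) had the smallest p of the members. By edgeR 0 passed when adjusted over the list alone (smallest 0.279; 9 had an unadjusted p under 0.05), while DESeq2 over all genes called Rps24, Rpl17 and Rplp0. Abundant transcripts as a class stood higher in the same libraries: of 347 protein-coding genes above 20 RPKM (without LOC257642), 262 (75.5%) were higher in MSCATV-Exo, with a median log2 fold change of 0.24, and without ribosomal protein genes it was 197 of 275 (0.22). The number was 228 of the 347 (median 0.14) with total-count scaling, 229 (0.15) when only features above the common RPKM level were tested and 225 (0.16) without MSC-Exo replicate 1. The ribosomal protein list lost its call without MSC-Exo replicate 1 (56 of 88 higher, median 0.18, adjusted p = 0.840), without MSCATV-Exo replicate 1 (0.219) and without MSCATV-Exo replicate 2 (0.0973), and kept it without MSC-Exo replicate 2 (76 of 88 higher, median 0.47, adjusted p = 0.000503). With total-count scaling its median was 0.18 (63 of 85 higher).

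No other fixed list was called. Extracellular matrix genes, typical of MSCs, came closest, with 17 of 21 members higher in MSCATV-Exo (median log2 fold change 0.21, camera adjusted p = 0.140). With limma on log2(RPKM + 1) 12 were higher (median 0.05), and of the 12 members above the common RPKM level 7 were higher (median 0.09). With total-count scaling 12 of the 21 were higher (median 0.11), and without MSC-Exo replicate 2 the median was 0.33 (15 higher). Among them Dcn, which encodes the matrix proteoglycan decorin, had 12 and 28 counts against 100 and 70 (log2 fold change 2.08 ± 0.72, SE), Mmp2 was at 0.78 ± 0.40, Col6a2 at 0.55 ± 0.29 (0.36 to 0.77 with a library left out) and Sparc at 0.37 ± 0.16. The median RPKM of the matrix list was 3.16 and 3.26 times that of olfactory receptor genes in the MSC-Exo libraries and 6.29 and 4.45 times in the MSCATV-Exo libraries. This rise was not particular to the matrix list. The ratio was 15.6 and 17.7 against 23.9 and 20.0 for protein-coding genes above 20 RPKM. For ribosomal protein genes it was 25.0 and 29.7 against 44.4 and 37.3. The olfactory receptor median itself was 2.48 and 2.36 RPKM against 1.71 and 2.28. Exosome biogenesis and cargo genes had 17 of 23 members higher (median 0.30, 0.19 with total-count scaling, adjusted p = 0.267), with Hsp90ab1 at 0.69 ± 0.26, Hspa8 at 0.45 ± 0.29, Tsg101 at 0.97 ± 0.64 and, lower, Cd82 at -0.63 ± 0.44 (SE; 109 and 135 counts against 81 and 77). With a library left out Hspa8 ranged from 0.21 to 0.72 and Tsg101 from 0.04 to 1.53. The exosome marker Cd81 was at 0.34 ± 0.58 and Cd9, with 2, 28, 41 and 25 counts, at 1.12 ± 1.28 (0.22 to 3.97 with a library left out), while Cd63 was at 0.06 ± 0.40 and at -0.04 with total-count scaling. Proliferation genes had 15 of 20 members higher (median 0.29, adjusted p = 0.267), with Aurkb at 1.45 ± 0.52. Their median was 0.11 without MSC-Exo replicate 1 (12 higher), 0.18 without MSC-Exo replicate 2 (14 higher) and 0.18 with total-count scaling. Targets of YAP and SRF had 9 of 14 higher (median 0.19, -0.01 with limma on log2(RPKM + 0.1), adjusted p = 0.661), with Myl9 at 0.56 ± 0.22 and Vcl at 0.63 ± 0.36 (0.36 to 0.93 with a library left out). Their median was 0.12 without MSC-Exo replicate 1, 0.07 without MSCATV-Exo replicate 2 and 0.09 with total-count scaling.

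Angiogenic and paracrine factors, which bear on the use of MSC exosomes in tissue repair, split evenly, with 9 of 18 higher and 9 lower (median 0.04, mean -0.00468, camera adjusted p = 0.882), and the median was -0.07 with total-count scaling. It was -0.00250 and 0.16 without MSC-Exo replicate 1 or 2, and 0.10 and -0.08 without MSCATV-Exo replicate 1 or 2. Vegfa was at 0.39 ± 0.44 (16.3 ± 1.95 against 21.5 ± 5.12 CPM), Vegfb at 0.52 ± 0.36, Fgf2 at -1.51 ± 1.02 and the adhesion molecule gene Icam1 at -0.24 ± 0.45 (SE). Group means in MSC-Exo and MSCATV-Exo were 4.27 and 5.19 RPKM for Vegfa and 7.68 and 6.03 for Icam1. All were under the cut of 8.17 RPKM, so the fold changes of these genes may not follow expression. With a library left out Vegfa ranged from 0.13 to 0.62, Vegfb from 0.26 to 0.83 and Icam1 from -0.52 to 0.00478, the last without MSCATV-Exo replicate 2. Genes of apoptosis and cell survival had 9 of 13 higher (median 0.27, adjusted p = 0.661), with Mcl1 at -0.70 ± 0.38 and Casp9 at 0.72 ± 0.48. Their median was 0.15 with total-count scaling, 0.15 without MSC-Exo replicate 1 (8 higher) and 0.55 without MSCATV-Exo replicate 1 (7 higher). Inflammatory genes had 4 of 13 higher, and their median of -0.04 differed in sign from the camera direction (adjusted p = 0.905). Sod2 was at 1.22 ± 0.50 and Cxcl10 at -1.43 ± 0.96 (-2.22 to -0.75 with a library left out). The inflammatory median was -0.16 with total-count scaling, 0.22 and -0.09 without MSC-Exo replicate 1 or 2, and 0.13 and -0.37 without MSCATV-Exo replicate 1 or 2. Nuclear genes of oxidative phosphorylation divided into 36 higher and 37 lower (median -0.01, mean 0.08, adjusted p = 0.777; Cox7c at 1.87 ± 0.67) and core histones into 20 and 15 (median 0.03, -0.06 with total-count scaling, adjusted p = 0.661). The oxidative phosphorylation median was -0.08 with total-count scaling, 0.04 and 0.20 without MSC-Exo replicate 1 or 2, and 0.19 and -0.15 without MSCATV-Exo replicate 1 or 2. The histone median was -0.12 and 0.40 without MSC-Exo replicate 1 or 2, and -0.21 and 0.14 without MSCATV-Exo replicate 1 or 2.

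**Figure D2:**
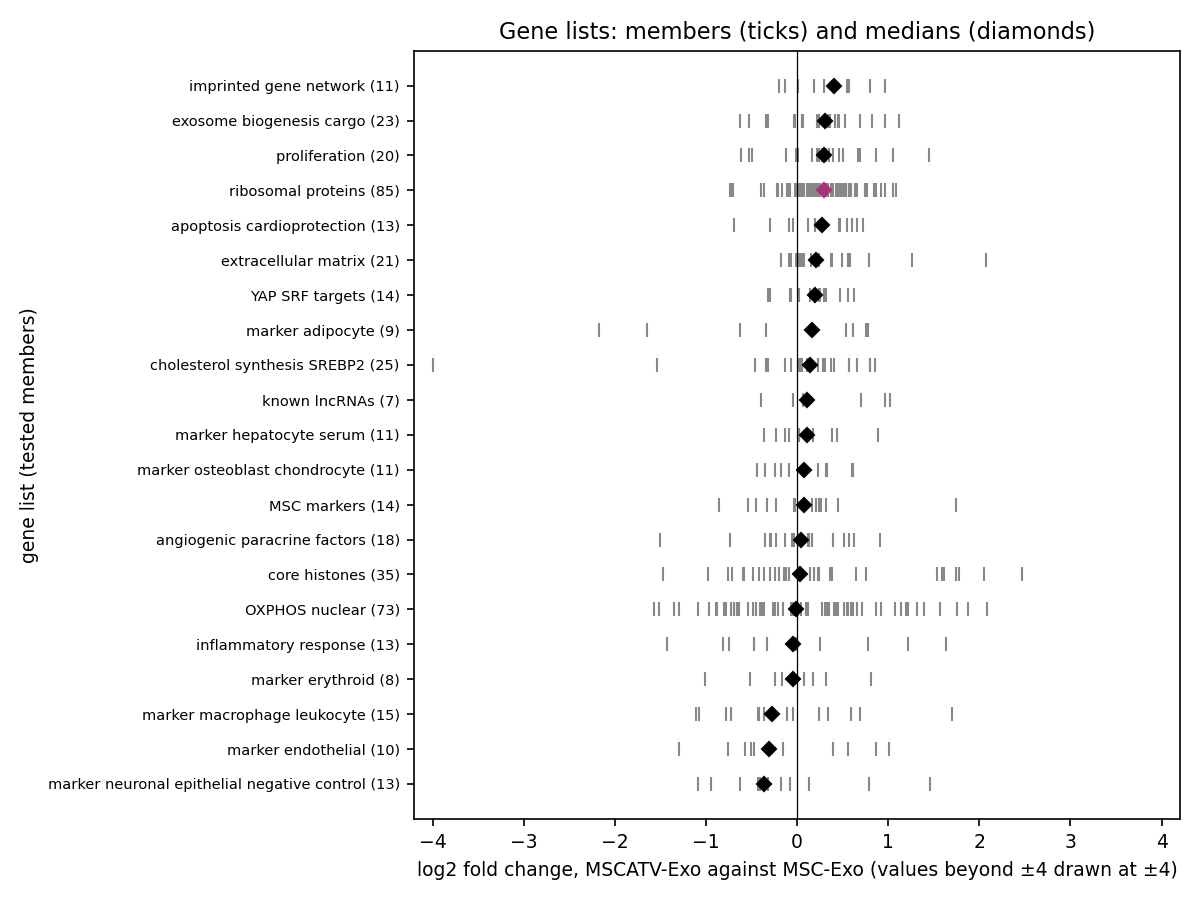
Log2 fold change of MSCATV-Exo against MSC-Exo for the tested members (grey ticks) and the median (diamonds) of fixed gene lists, with the number of tested members in brackets; the ribosomal protein list, called by camera, has a coloured diamond. The ribosomal protein median was 0.29 and that of the cholesterol synthesis list 0.14.

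No list of markers of the MSCs or of other cell types that marrow cultures can hold was called. MSC markers had 7 of 14 members higher (median 0.07, adjusted p = 0.848), and the median was -0.02 with total-count scaling. The integrin gene Itgb1 was at 0.32 ± 0.23 (SE; 0.21 to 0.43 with a library left out), Ly6al at 1.74 ± 1.13 (0.84 to 4.49), Prrx1 at -0.45 ± 0.40 (-0.80 to 0.0000986) and Vcam1 at -0.85 ± 0.86. Leukocyte and macrophage markers had 5 of 15 higher (median -0.28, adjusted p = 0.848), erythroid markers 4 of 8 (-0.04, 0.848; 0.02 with limma on log2(RPKM + 0.1)), endothelial markers 4 of 10 (-0.31, 0.905) and osteoblast and chondrocyte markers 6 of 11 (0.07, 0.848; -0.03 with total-count scaling). Adipocyte markers had 5 of 9 higher, with a median of 0.16, a mean of -0.22 and a downward camera direction (adjusted p = 0.905), with Lpl at -2.18 ± 0.92 (-4.11 to -1.38 with a library left out) and Cfd at 0.78 ± 0.64 (0.27 to 1.16). Without MSC-Exo replicate 1, MSC-Exo replicate 2, MSCATV-Exo replicate 1 and MSCATV-Exo replicate 2 in turn, the median of MSC markers was -0.06, 0.14, 0.26 and -0.09. In the same order that of leukocyte and macrophage markers was -0.04, -0.06, -0.09 and -0.39, and that of erythroid markers 0.42, 0.22, -0.00554 and -0.24. Endothelial markers were at -0.07, -0.31, 0.08 and -0.49, adipocyte markers at -0.28, 0.50, 0.13 and 0.00169, and osteoblast and chondrocyte markers at 0.00127, 0.07, 0.04 and 0.15. With total-count scaling the erythroid median was -0.14 and the adipocyte median 0.05. Hepatocyte and serum protein genes had 7 of 11 higher (0.11, 0.848), and their median was -0.06 with limma on log2(RPKM + 1), 0.02 with total-count scaling and 0.24 without MSCATV-Exo replicate 1. A list of neuronal, epithelial, islet and cardiac genes, which stand for other tissues, had 3 of 13 higher (median -0.37, adjusted p = 0.746), and 5 of 13 without MSCATV-Exo replicate 2 (median -0.04). Of the structural RNAs, 3 were tested, too few for a list test, with Rmrp at 0.46 ± 0.17 (SE; 0.29 without MSC-Exo replicate 1) and Rn7sl1 at -0.18 ± 0.29 (-0.44 to 0.13 with a library left out).

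The 45S and 28S rRNA genes Rn45s and Rn28s held the most counts of all genes on average. Features typed as rRNA took 32.9 ± 0.0995% of gene counts in MSC-Exo and 35.8 ± 3.47% in MSCATV-Exo (SD, n = 2), with 38.2% in MSCATV-Exo replicate 1 and 33.3% in replicate 2. Rn45s averaged 159691 ± 1194 CPM in MSC-Exo and 187426 ± 29513 in MSCATV-Exo. Without MSCATV-Exo replicate 2 the genes Rn45s (log2 fold change 0.39), Rn28s (0.38) and Rn18s (0.46) passed the edgeR threshold, and with any other library left out they did not. Rn18s and Rn28s lie inside it on chromosome 14. Their sum came to 99.5% to 99.7% of its counts, so these reads were counted more than once. Protein-coding genes took 44.7 ± 0.687% against 43.8 ± 2.25%, features typed as lncRNA 7.39 ± 0.351% against 6.63 ± 0.482% and those typed as pseudogene 11.7 ± 0.0724% against 10.6 ± 0.681% (SD, n = 2). Features typed as lincRNA were apart from these, at 1.60 ± 0.0483% against 1.47 ± 0.0463%, as were processed and unprocessed pseudogenes. With 2 libraries against 2 the smallest two-sided exact permutation p is 0.333, so that test could not pass 0.05, and no other test of the shares was run.

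Below the few abundant transcripts, RPKM values lay close to a common level. Of 22633 protein-coding genes, 73.1% had a mean RPKM within 2-fold of the median of 4.76, and 348 (1.54%) were above 20. Olfactory receptor genes, which marrow stroma has no known use for, had a median RPKM of 1.71 to 2.48 over the 4 libraries, and the other-tissue list had 5.99 to 8.04. Extracellular matrix genes had 7.72 to 10.8, and ribosomal protein genes 62.0 to 84.9. Above a mean of 8.17 RPKM, 3 of 14 tested MSC markers, 3 of 18 angiogenic and paracrine genes and 3 of 25 cholesterol synthesis genes remained. Log2 fold changes of genes near the common level may not follow expression. H19, at 17.3 to 38.7 RPKM, stood above the median of features typed as lncRNA, which was 2.75 to 3.62.

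**Figure D3:**
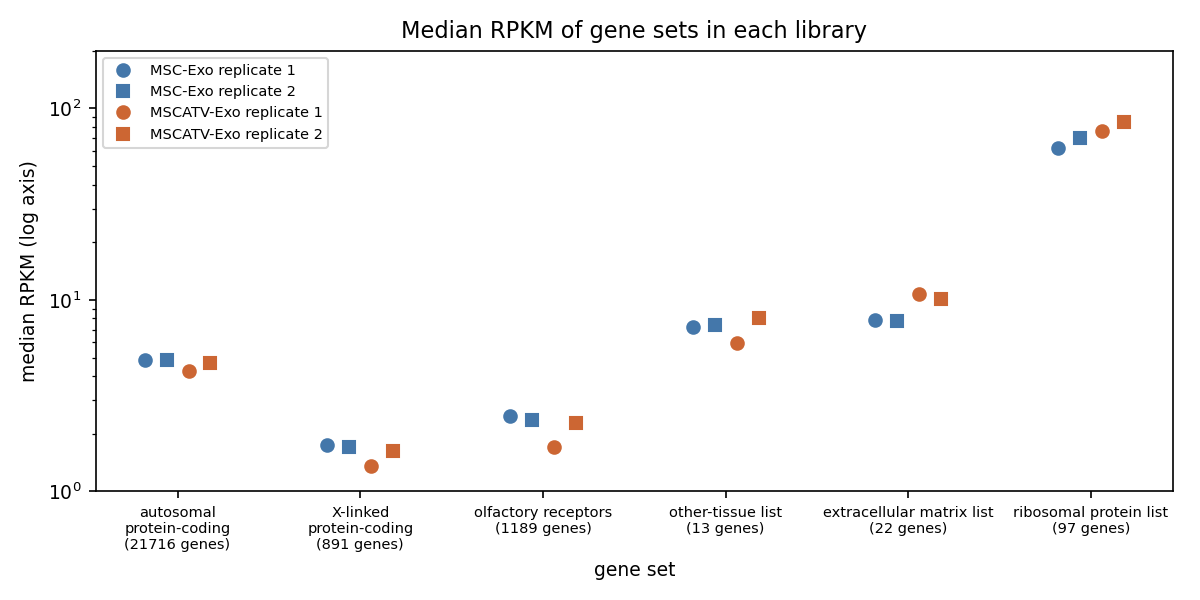
Median RPKM (log axis) of 6 gene sets in each of the 4 libraries, coloured by group. Ribosomal protein genes lay at 62.0 to 84.9 RPKM, olfactory receptor genes at 1.71 to 2.48 and extracellular matrix genes at 7.72 to 10.8.

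The authors' own comparison, deposited with a p-value and q-value for each feature, held many more calls. At q under 0.05 it listed 13053 of 38021 genes (34.3%), 4722 higher and 8331 lower in MSCATV-Exo, and 5563 of 16059 ncRNAs (34.6%), of which 69.1% were lower. The median log2 ratio in these tables was -0.11 for genes and -0.12 for ncRNAs, against -0.01 and -0.02 in the edgeR comparison with TMM scaling. DESeq2 called 51 genes higher and 55 lower, and 6 ncRNAs higher and 25 lower. The deposited list of 1782 differential ncRNAs, 450 higher and 1332 lower, held the features of the full table with q under 0.001 and at least a 1.5-fold ratio. In the authors' tables H19 stood at a mean of 20.7 RPKM in MSC-Exo and 37.6 in MSCATV-Exo (log2 ratio 0.86, q = 5.07e-13), ranked 99 of 38021 genes by p, and its transcript ranked 65 of 16059 ncRNAs. Vegfa (log2 ratio 0.28, q = 0.283) and Icam1 (-0.35, q = 0.188) were not called there.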

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

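Alternatives that left out rRNA features or kept only features above the common RPKM level were chosen after the data were seen, and the other alternatives given here were chosen before the data were examined. The number of genes past the threshold was 0 by edgeR (1236 at an unadjusted p under 0.05) and also 0 with RLE factors, total counts, a mean of at least 1 CPM, limma with either pseudocount and without rRNA features. It was 106 with DESeq2, 8 with no filter on low counts, 2 with only features above the common level (Fam111a and LOC689258, of 4251 tested), 13053 by the authors' calls and 1 to 168 when a library was left out, 168 without MSCATV-Exo replicate 2. For ncRNAs the count of 0 (463 at an unadjusted p under 0.05) became 31 with DESeq2, 7 with no filter, 5563 by the authors' calls and 0 to 69 when a library was left out, and stayed at 0 in the other alternatives except the replicate block. Where a library was left out, the lone library of its group was assumed to vary like the other group. The cause of these differences was not tested. The replicate numbers pair nothing in the labels, and differences between replicates 1 and 2 were uncorrelated between the groups (-0.00 across genes). With the replicate block 4 genes were called, LOC257642, Fam111a and the models ENSRNOG00000052862 and ENSRNOG00000053717, and 2 ncRNAs. The call of 1 list became 0 with an estimated correlation (ribosomal protein adjusted p = 0.916), 0 with fry (0.603) and 0 to 1 when a library was left out (0.000503 to 0.840, lost without MSC-Exo replicate 1 and without either MSCATV-Exo library), and it was kept with RLE factors, a mean of at least 1 CPM, the replicate block (0.0104), without rRNA features and above the common level (0.00342). Of 92 log2 fold changes of single features, 362 of 368 values with a library left out and 859 of 863 values under the other alternatives kept their direction, and 31 and 55 of them passed the threshold. Many of these features were named because their groups did not overlap, and leaving out a library can then turn a direction only through the scaling, so the count says little about stability. Cd63, at 0.06, was at -0.0436 with total counts, -0.0239 and -0.0242 with limma at pseudocounts of 1 and 0.1, -0.0456 with only features above the common level and from -0.14 to 0.29 when a library was left out. Icam1 ranged from -0.52 to 0.00478 (the last without MSCATV-Exo replicate 2), Prrx1 from -0.80 to 0.0000986 and Rn7sl1 from -0.44 to 0.13 (the last of both without MSC-Exo replicate 2), and Mir155hg from -0.29 (without MSCATV-Exo replicate 1) to 1.86 when a library was left out. ENSRNOG00000052862 ranged from -0.67 without MSCATV-Exo replicate 2 to 12.69 without MSC-Exo replicate 2, the latter a fitted value against a library at 0 and no estimate of size. The cause of these reversals was not tested. Quantile normalisation was not run, since counts were deposited. In simulated data 2-fold changes at 32 CPM or more were mostly not detectable, with 2 of 100 recovered for genes and 0 of 100 for ncRNAs.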

Other observations

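DESeq2 called further genes as higher in MSCATV-Exo that the edgeR test did not call. Those in this paragraph were chosen after their values were seen, and no theme among them was tested. They were the microtubule-associated protein gene Map4 (log2 fold change 0.54, adjusted p = 3.03e-05 by DESeq2), the tropomyosin gene Tpm4 (0.64, 0.0141), the ferritin heavy chain gene Fth1 (0.69, 0.00849), the poly(A)-binding protein gene Pabpc1 (0.59, 0.0253), the matrix metalloproteinase gene Mmp14 (1.42, 0.0128), the laminin gene Lamb1 (1.27, 0.0437) and the IGF-binding protein gene Igfbp4 (1.28, 0.0314). Of the 106 DESeq2 calls, 23 were above 20 RPKM, and 19 of these were higher in MSCATV-Exo. Called or not, 265 of 347 protein-coding genes above 20 RPKM (76.4%) were higher by DESeq2. A further 29 of the 106 had a group with 0 counts in both libraries.

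The Ensembl models ENSRNOG00000052862 and ENSRNOG00000053717, also chosen after their values were seen, took most of their reads from MSCATV-Exo replicate 2 and averaged 149 and 158 CPM in MSCATV-Exo against 7.85 and 10.8 in MSC-Exo. The mitochondrial rRNA genes Rnr1 and Rnr2 had 0.878 to 2.15 and 1.14 to 2.89 RPKM over the 4 libraries. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.742 between the MSC-Exo libraries, 0.685 between the MSCATV-Exo libraries and 0.684 to 0.742 between libraries of different groups. Pairs with MSCATV-Exo replicate 1 were at 0.684 to 0.713 and the other 3 pairs at 0.711 to 0.742, and this library also had the highest rRNA share (38.2%) and the fewest genes with a count (34813).

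In what follows, the test on neuronal, epithelial, islet and cardiac genes was chosen only after the result was seen, and the other bounds were set before the tested values were seen. The near-common RPKM of most genes was weighed against genomic DNA among the reads and against RNA of the cultured cells as the source of most reads. The other-tissue genes had a median 1.45 to 1.77 times that of all protein-coding genes, which is consistent with reads that do not follow expression, genomic DNA being a candidate. Olfactory receptor genes reached 0.415 to 0.522 of the protein-coding median, where 0.5 in every library was set for genomic DNA and less than 0.1 against it, and X-linked genes 0.320 to 0.362 of the autosomal median, below the range of 0.4 to 0.65 set for cells with a single X chromosome, so neither decided. Extracellular matrix genes stood 3.16 to 6.29 times above olfactory receptor genes, where 10 times was set for RNA of the cells as the source of most reads and 2 times against it, so that source also stays open. Ribosomal protein genes, at 62.0 to 84.9 RPKM, were far above the common level, and no biological explanation was tested.

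The far larger number of genes in the authors' tables than in the replicated count test may come from a test on reads that leaves out the spread between libraries of the same group. An exact binomial test on reads called a mean of 19069 of 38274 genes between libraries of the same group and 19179 between libraries of different groups, a ratio of 0.994, where at least 0.5 had been set for this explanation. The authors' test is not stated, so whether it was of this kind stays open. An effect of atorvastatin on part of those genes is not excluded by the ratio.

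The higher H19 level in both MSCATV-Exo libraries was weighed against a larger share of RNA above the common level in these libraries and against chance spread. Its log2 fold change stood at percentile 95.7 (95% Wilson interval 93.4 to 97.2) of 461 genes of similar RPKM, whose median was 0.18. The interval holds the bound of 95 set in advance, so a general shift of abundant RNA and a difference of H19 itself cannot be told apart. It treats the genes as independent and leaves out the spread between libraries. The log2 fold change of H19 was 0.76 to 1.20 with a library left out. In splits of the libraries that cross the groups, 4.56% and 4.77% of these genes had as large a separated difference, against 5.42% in the real split, just under the 5% set for chance spread and above the 1% set against it. An effect of atorvastatin on H19 in exosomes therefore remains a hypothesis that 2 libraries per group leave open.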
